A study of Mus musculus with 28 samples.

How the data were processed

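The data were 28 arrays of RNA from retinal amacrine cells of mice, sorted by fluorescence into samples of 200 cells. Arc amacrine cells carried EGFP from an Arc transgene, and starburst amacrine cells carried RFP through a Chat-cre driver. Each sample came from 1 retina per the labels. The labels describe the Arc-EGFP mice as the F2 generation of FVB/N-Swiss Webster hybrids, known to harbour a recessive mutation that causes photoreceptor degeneration, crossed to C57BL/6J.

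The authors processed the arrays with R 2.11.1 and RMA (background correction, normalization between arrays and summary over probes), and the labels name genome build mm8. The deposited values are on the log2 scale. The base of the logarithm is not stated in the labels. It was taken from RMA's convention and from the highest value of 11.15, which lies above 11.09, the natural logarithm of the largest 16-bit scanner value. Which arrays were normalized together, and whether probes were filtered or a batch correction was applied, is not stated. The series speaks of biological triplicates, but the table used here holds 1 Arc array per day, with 2 at P6, so whether an Arc value stands for 1 sample or a mean of several is open. Arrays of P0 were not analysed here.

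The table held 15170 transcript clusters, of which 13720 carried 1 gene symbol, 869 carried several and 581 carried none. Those with 1 symbol were kept. For 102 genes with more than 1 cluster, the cluster with the highest mean over all 28 arrays was used, which left 13617 genes. No gene was removed for a low value. Gene symbols were used without chromosomal positions, which were not analysed here. Array medians lay between 3.34 and 3.51 in the 22 Arc arrays and between 3.53 and 3.64 in the 6 starburst arrays. The 708 measured olfactory receptor genes, chosen as a background set after the values were seen, had a median of 2.20 in Arc and 2.32 in starburst cells, and 95th percentiles of 3.47 and 3.91. Signals near this background were kept, and no gene was called present or absent.

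All gene tests used limma 3.58.1 in R 4.3.3, with eBayes(trend=TRUE), two-sided, and Benjamini-Hochberg adjustment over the 13617 genes at 0.05. The age trend in Arc cells was a linear term in days over the 21 arrays of P1 to P20, reported as the fitted change between those days. P43 was held out. The same 21 arrays formed 3 windows of 7 arrays each, early (P1 to P6), middle (P7 to P13) and late (P14 to P20). Starburst P18 was compared with P3 over the 6 starburst arrays alone. For the comparison of cell types a fit over 12 arrays held starburst P3, starburst P18, Arc P2 to P4 and Arc P17 to P19, with 3 arrays each. The neighbouring days stood in for Arc replicates. The difference between the developmental changes of the cell types was tested as an interaction in that fit. All Arc arrays carry the batch label "A and B" and all starburst arrays the label "B", so cell type, mouse line, fluorophore and batch cannot be told apart.

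The Pearson correlation across genes of each Arc array with the P43 array was related to age with a two-sided permutation test of 100000 resamples. Overlap between the Arc trend and the starburst change was tested per direction with Fisher's exact test. A total of 24 gene lists was fixed, covering cell cycle, neurogenic transcription factors and Notch, neurite growth and guidance, synaptic vesicle and release, GABA and glycine receptors, glutamate receptors, voltage-gated ion channels, oxidative phosphorylation, cholesterol synthesis, immediate early genes, and markers of pan-amacrine, starburst amacrine, amacrine subtype, rod, cone, bipolar, Muller glia, ganglion, horizontal, microglia, endothelial and mural, astrocyte, erythrocyte and lens cells. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

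The named genes were, per comparison, the 12 highest and the 12 lowest changes among genes past the threshold with a mean over the arrays of the fit above the median of all genes and a symbol that is not a placeholder; in comparisons of 3 against 3 arrays the groups also had to be free of overlap. Members of the lists could be named too, and Arc, Chat, Slc18a3 and Slc5a7 were reported first. The comparisons, lists and naming rule were fixed before the data were examined. The choice among these genes for the text was made after their values were seen.

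The pipeline was tested on simulated data of the same size, with 200 changed genes and independent noise. A log2 change of 1 was recovered for 100% of such genes in the age trend, 94.0% in middle against early, 97.0% in late against middle, 59.7% in starburst P18 against P3, 73.1% and 77.6% in the P3 and P18 comparisons of cell types and 49.3% in the interaction. At a log2 change of 0.5 recovery was 7.46% in starburst P18 against P3 and 4.48% in the interaction. False calls among the unchanged genes numbered 15 in the age trend, 8 in middle against early and 14 in late against middle. The other comparisons had 0 to 7.

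Alternatives were a filter on dim genes, cyclic loess, no intensity trend, all transcript clusters, array weights, a minimum log2 change of 1, other forms of the age term and other windows, a replicate block, other Arc days as partners, and leaving out each array in turn. Quantile normalization, centring of each array on its median, days P1 to P16 alone, and the lists without single arrays were added after the values were seen. Each group comparison was also repeated with other splits of its arrays, 100 where that many could be drawn, the real one included.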

Results

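Expression was measured in 2 kinds of retinal amacrine cell during the first postnatal weeks. Arc amacrine cells were represented by 21 arrays between P1 and P20, 1 for each day and 2 at P6, and by 1 array at P43. Starburst amacrine cells, the cholinergic interneurons of the retina, were represented by 3 arrays at P3 and 3 at P18. Values are log2 expression, and the replicates of starburst cells correlated across genes with r between 0.950 and 0.966, as against 0.974 for both Arc arrays of P6. There were no replicates of other Arc days. Background, taken as the 95th percentile of olfactory receptor genes, was 3.47 in Arc and 3.91 in starburst cells. Where the mean of a gene lay below this in one of the groups compared, the difference of the group means is to be read as a lower bound. Changes in the age trend are fitted lines and not bounds.

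The genes of the sorting lines and of acetylcholine transport were examined first. Chat, the enzyme that makes acetylcholine (transcript cluster 6823797), had a mean of 5.32 ± 0.41 (SD, n = 3) in starburst cells at P3 and 7.19 ± 0.34 (SD, n = 3) at P18, and 2.76 in Arc cells of P17 to P19. Slc18a3, the vesicular acetylcholine transporter, stood at 6.78 ± 0.17 (SD, n = 3) at P3 and 7.55 ± 0.35 (SD, n = 3) at P18 in starburst cells, and at 2.44 in Arc cells of P17 to P19. Slc5a7, the choline transporter (6856133), was near background at P3 in starburst cells, with 2.46 ± 0.33 (SD, n = 3), and reached 7.85 ± 0.23 (SD, n = 3) at P18. Arc, the gene whose promoter drives EGFP, had a mean of 5.71 ± 0.29 (SD) in the 7 early and 5.79 ± 0.12 (SD) in the 7 late Arc arrays. In starburst cells Arc stood at 4.33 ± 0.54 (SD, n = 3) at P3 and 4.71 ± 0.44 (SD, n = 3) at P18.

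The age trend asks which genes change as Arc cells mature. Among the genes with the largest falls was Dcx, a microtubule-associated protein of migrating neurons (transcript cluster 7019970), which fell by 5.98 ± 0.45 (SE, 21 arrays) on the log2 scale between P1 and P20, at adjusted p = 2.11e-10. Sox4, a transcription factor of immature neurons, fell by 4.10 ± 0.22 (SE), Dpysl3, a growth cone protein, fell by 4.50 ± 0.22 (SE), and Stmn2, a regulator of microtubules in growth cones, fell by 3.64 ± 0.36 (SE). Crabp1, a retinoic acid binding protein, fell by 4.67, Rnd3, a small GTPase, fell by 3.69, and Tac1, the precursor of substance P, fell by 2.91. Genes that rose included Aldoc, a glycolytic aldolase (6782694), with a change of 6.48 ± 0.33 (SE, 21 arrays) at adjusted p = 4.47e-13. Sparcl1, a secreted matricellular protein, rose by 4.59 ± 0.22 (SE), Rasgrp1, an activator of Ras, by 4.50 and Olfm3, a secreted olfactomedin, by 4.99. Pcp4, a calmodulin regulator, rose by 4.31, Synpr, a synaptic vesicle protein, by 4.03 and Vsnl1, a neuronal calcium sensor, by 4.03. Gnat1, the transducin subunit of rod photoreceptors, rose by 5.13 ± 0.49 (SE). For 21 of the 24 genes named by rule, all 7 late arrays lay beyond all 7 early arrays. The exceptions were Pcp4 with 6, Tac1 with 4 and Socs2, a suppressor of cytokine signalling that fell by 2.91, with 2 late arrays.

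In all, 5137 of 13617 genes passed the test, 2005 higher and 3132 lower with age, and 691 rose and 298 fell at least 2-fold. The median change of all genes was -0.13, and cyclic loess moved it to -0.02 and the split to 2048 higher and 1728 lower. With each array centred on its median the split was 2423 higher and 1478 lower. The excess of lower calls therefore depended on the scaling, and so did its direction. With P1 to P16 alone, and so with fewer arrays, 1966 genes passed, 1150 higher and 816 lower, at a median change of -0.14, and there Socs2 and Tac1 no longer did; over all alternatives the adjusted p ranged up to 0.132 for Socs2 and 0.1205 for Tac1.

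**Figure D1:**
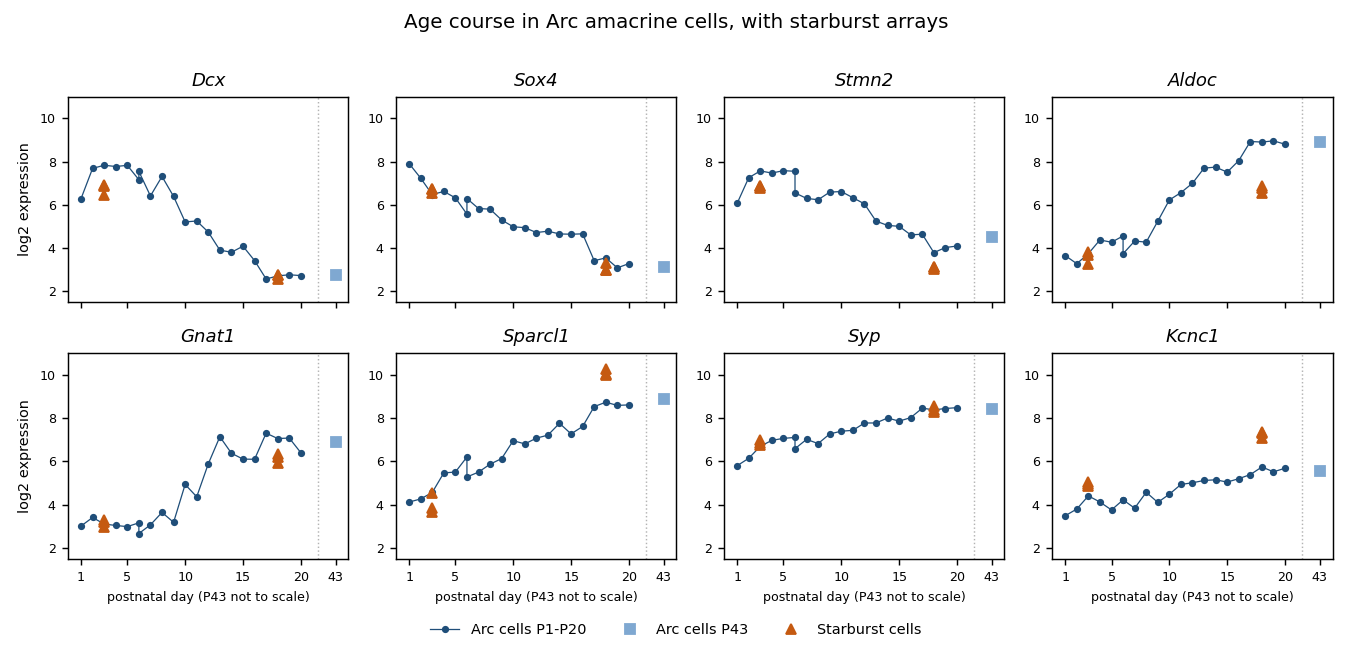
Log2 expression of 8 genes in each array against postnatal day, with Arc arrays of P1 to P20 joined by a line (both P6 arrays shown), the Arc P43 array as a square placed off scale, and starburst arrays as triangles, 3 at P3 and 3 at P18. Dcx, Sox4 and Stmn2 fell, while Aldoc, Gnat1, Sparcl1, Syp and Kcnc1 rose in both cell types.

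Genes of synaptic release and of excitability rose as groups in Arc cells. Of 22 measured genes of the synaptic vesicle and release list, 16 were higher and 2 lower (17 and 2 adjusted over the list alone), among them Syn2, a synapsin (2.95), Nsf, the membrane fusion ATPase (2.86), Snap25, a core SNARE protein (2.61), and Syp, synaptophysin (2.40). Of 24 voltage-gated ion channel genes, 15 were higher and 3 lower (15 and 3 adjusted over the list alone), including the potassium channel genes Kcnab1 (3.21) and Kcnc1 (2.08), while the immature sodium channel gene Scn3a fell by 1.76. Both lists were called by camera with the preset correlation (adjusted p = 2.86e-13 and 1.84e-08) and with an estimated correlation (adjusted p = 0.0215 and 0.00962). The remaining lists called with the preset correlation were not called with an estimated one. Among them, 14 of 23 oxidative phosphorylation genes were higher and none lower, such as Sdha (1.59) and Cox4i1 (1.26), at adjusted p = 1.29e-06 and 0.181 with an estimated correlation. Of 14 GABA and glycine receptor genes 7 were higher and 1 lower (7 and 2 adjusted over the list alone), including Glrb (2.87) and Gabrb2 (2.67) against Glra2 (-0.91), at adjusted p = 0.0213 and 0.297 with an estimated correlation. Glutamate receptor genes were mixed, with 6 of 15 higher and 3 lower (6 and 5 adjusted over the list alone), at adjusted p = 0.0853.

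Lists of earlier developmental programs had more genes lower than higher with age in Arc cells. Neurogenic transcription factors and Notch had 13 of 21 genes lower and none higher (14 adjusted over the list alone), among them Sox11 (-2.14) and the proneural factors Neurod4 (-1.97) and Neurod1 (-1.76), at adjusted p = 0.0013 and 0.364 with an estimated correlation. Neurod4 lost its call with P1 to P16 alone (adjusted p = 0.146, the highest over its alternatives). Of 25 genes of neurite growth and guidance 11 were lower and 3 higher (15 and 3 adjusted over the list alone), with Tubb2b, a tubulin of young neurons, at -2.42 and the guidance gene Sema3a higher at 1.01, at adjusted p = 0.0048 and 0.238 with an estimated correlation. Cell cycle genes had 13 of 24 lower (14 adjusted over the list alone), such as the replication helicase gene Mcm7 (-1.27), at adjusted p = 0.0013 and 0.181 with an estimated correlation. Only 5 of the cell cycle genes were lower after cyclic loess, where the list's median stood 0.15 below that of all genes. Amacrine subtype genes had 9 of 19 lower and 1 higher (9 and 1 adjusted over the list alone), among them Lhx9 (-0.87) and Npy (-1.35), at adjusted p = 0.0252 and 0.181 with an estimated correlation.

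Markers of other retinal cells moved in different directions in Arc cells. Rod photoreceptor genes had 11 of 18 higher and none lower (11 adjusted over the list alone), at adjusted p = 1.5e-05 and 0.181 with an estimated correlation. Beside Gnat1, the phototransduction gene Pde6a rose by 1.25 and the outer segment gene Prph2 by 1.04. Bipolar genes were 3 of 14 higher and 5 lower (3 and 6 adjusted over the list alone), the highest being Prkca, a protein kinase C (3.56), and after cyclic loess 3 were higher and none lower. Cone genes were 2 of 13 lower and none higher, which became 2 higher and none lower after cyclic loess. Of 14 Muller glia genes 3 were higher and 4 lower (3 and 2 after cyclic loess), of 11 ganglion cell genes 2 and 4 (2 and 1), and of 7 horizontal cell genes 1 and 4 (1 and 2). Microglia genes had 3 of 10 lower (4 adjusted over the list alone), endothelial and mural genes 5 of 13 and lens genes 3 of 10, with none higher; after cyclic loess 0, 1 and 2 genes of these lists were lower by limma. In the astrocyte list Aldoc was the 1 of 5 genes called (1 higher and 2 lower adjusted over the list alone), and the 2 measured erythrocyte genes were not called except over the list alone, where both were lower. Of these lists camera called rod alone and did not test the erythrocyte list; for bipolar, Muller glia, ganglion and astrocyte genes the median change was negative and the mean positive. Pan-amacrine genes were 3 of 13 higher and 6 lower, with Gad1, the GABA-synthesizing enzyme, at 2.86 and the transcription factors Pax6 (-0.60) and Meis2 (-1.14) lower. Starburst genes had 2 of 8 lower, which were not called over the list alone. Immediate early genes had 2 of 18 higher and 4 lower, and cholesterol synthesis genes 3 of 13 higher, at adjusted p = 0.971 and 0.117.

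**Figure D2:**
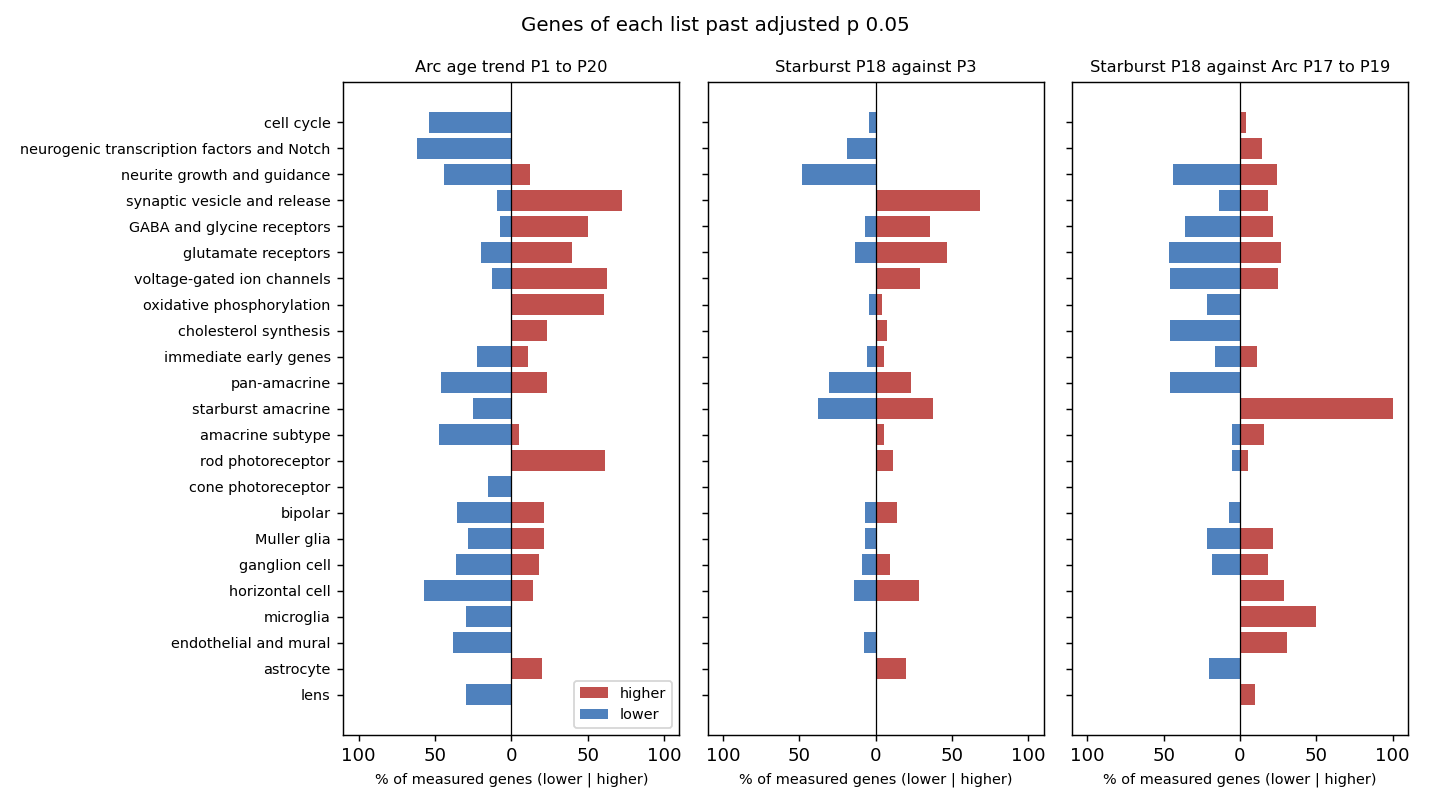
Share of the measured genes of each list (percent) that passed adjusted p of 0.05, higher to the right in red and lower to the left in blue, for the Arc age trend, starburst P18 against P3, and starburst P18 against Arc P17 to P19. Synaptic vesicle genes were higher with age in 16 of 22 measured genes in Arc cells and 15 of 22 in starburst cells, and all 8 starburst genes were higher in starburst cells.

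The windows ask which genes differed between neighbouring stretches of days. Their counts past the threshold do not compare the sizes or the pace of the change. A quadratic term of age, which tests for some forms of a changing pace only, called 0 genes by limma. At an unadjusted p under 0.05 it had 176 genes, fewer than the 681 that chance gives. Its 0 calls therefore do not show a constant pace. A cubic term called 49 genes, with 1477 unadjusted, so a changing pace is not excluded. Both terms are given under other observations. Between the middle and the late window 914 genes changed, 642 higher and 272 lower, of which 79 and 14 by at least 2-fold. Aldoc rose by 2.51 ± 0.43 (SE) and Glul, glutamine synthetase, by 1.58 ± 0.28 (SE), at adjusted p = 0.00111 and 0.00148. Dcx fell by 2.45 ± 0.40 (SE), Dpysl3 fell by 1.80 and Stmn2 fell by 1.73. For Glul, Mgarp, a mitochondrial protein, and Thy1, a neuronal surface glycoprotein, all 7 late arrays lay above all 7 middle arrays, as in 11 of the 24 genes named by rule in one direction or the other. The count was 580 without the P7 array and 605 without the P8 array. It was 1511 with array weights (880 higher, 631 lower) and 2181 with the other windows, where the split was near even (1141 higher, 1040 lower).

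Between the early and the middle window 67 genes passed the test, 47 higher and 20 lower, with adjusted p close to the threshold. Aldoc rose by 1.96 ± 0.43 (SE), Rasgrp1 by 1.46 ± 0.29 (SE) and Got1, the cytosolic aspartate transaminase, by 1.11 ± 0.20 (SE), while Dpysl3 fell by 1.36 ± 0.26 (SE) and Cdh2, N-cadherin, fell by 1.02 ± 0.20 (SE), with adjusted p between 0.0396 and 0.0473 for the 24 genes named by rule. For Dpysl3 and Zfp57, a zinc finger protein that fell by 1.06, all 7 middle arrays lay below all 7 early arrays. This count rested on single arrays. It was 0 without any one of P1, P2, P3, P4, P5, P10, P11, P12, P13, P17 or P6 replicate 1, while it was 272 without P6 replicate 2, 222 without P7, 198 without P8, 105 without P15, 25 without P16, 20 without P18 and 30 without P20. It was also 0 with array weights and with the other windows, and 1478 genes had an unadjusted p under 0.05.

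Arc arrays came closer to the P43 array with age. The Pearson correlation across genes with P43 was 0.891 at P1, 0.965 at P10 and 0.980 at P20. Across the 21 arrays this similarity was related to age with Pearson r = 0.921 and Spearman rho = 0.985, both with a permutation p of 1e-05, the smallest that 100000 resamples can give. Without the arrays of P1 and P20, farthest from the median age, r was 0.947. Correlations across genes by rank, or over genes above the median mean, gave r = 0.904 and 0.930 with age. Genes within an array are not independent replicates.

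**Figure D3:**
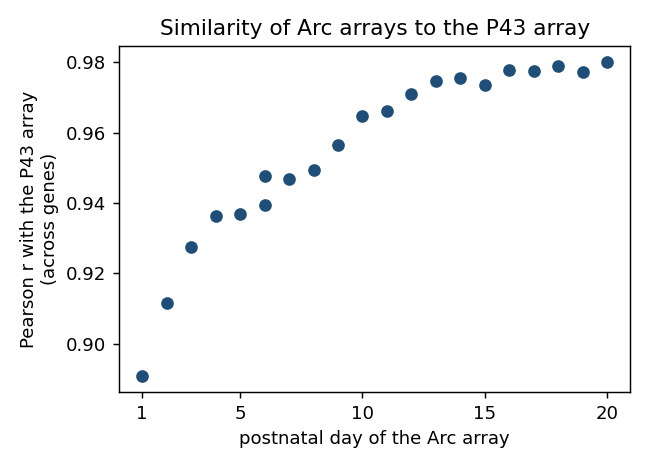
Pearson correlation across 13617 genes of each Arc array with the Arc P43 array, against the postnatal day of the array, 1 point per array. The values ran from 0.891 at P1 to 0.980 at P20.

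Starburst cells were compared between P3 and P18 to ask what changes as they mature. Slc5a7, the choline transporter, rose by at least 5.38 ± 0.20 (SE, n = 3 and 3) at adjusted p = 1.87e-06, being below background at P3, and Chat rose by 1.87 at adjusted p = 0.00148. Slc18a3 had a change of 0.77 at adjusted p = 0.0442, a call that was lost after quantile normalization (0.68, adjusted p = 0.0564), with a replicate block, and without any 1 of 5 of the 6 arrays, with adjusted p up to 0.148 over all alternatives. Sparcl1 rose by 6.10 ± 0.23 (SE). Slc24a4, a sodium and calcium exchanger, rose by at least 4.50 and Rgs6, a regulator of G protein signalling, by at least 4.38, both below background at P3, and Chrm4, a muscarinic acetylcholine receptor, by 3.53. Among genes that fell, Vcan, the proteoglycan versican (6814956), fell by 4.99 ± 0.15 (SE), Has2, a hyaluronan synthase, fell by 3.67, Dcx fell by 4.06, Stmn2 fell by 3.73 and Sox4 fell by 3.58. Megf10, a receptor in the spacing of starburst cells, fell by 3.50 ± 0.16 (SE), and Chrna4, a nicotinic receptor subunit, fell by 3.12. In all, 1178 genes passed the test.

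Of those genes, 648 were higher and 530 lower at P18, of which 368 and 237 by at least 2-fold; a fit over all 28 arrays turned this balance, with 1110 higher and 1412 lower. The synaptic vesicle list had 15 of 22 genes higher and none lower (17 adjusted over the list alone), including Sncb, beta-synuclein (2.61), and Sv2a, a vesicle glycoprotein (2.38), at adjusted p = 2.57e-14 and 0.102 with an estimated correlation. Neurite growth and guidance had 12 of 25 lower and none higher (12 and 1 adjusted over the list alone), with Sema3a at -2.43, at adjusted p = 4.44e-07 and 0.102 with an estimated correlation. Voltage-gated ion channels had 7 of 24 higher (10 and 2 lower adjusted over the list alone), with Kcnab1 at 3.34, at adjusted p = 1.1e-04 and 0.102 with an estimated correlation. Of 15 glutamate receptor genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone), such as Gria3 (3.22) and Grm8 (3.39) against Gria1 (-2.04), at adjusted p = 0.00303 and 0.164 with an estimated correlation. Of 14 GABA and glycine receptor genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone), with Glra4 at 2.75 and Gabra3 at -1.54, at adjusted p = 0.0143 and 0.254 with an estimated correlation. Neurogenic factors had 4 of 21 lower (5 adjusted over the list alone), at adjusted p = 0.00303 and 0.199 with an estimated correlation. Rod genes had 2 of 18 higher (8 adjusted over the list alone), Gnat1 (2.99) and Sag (1.03), at adjusted p = 2.08e-05 and 0.102 with an estimated correlation. Sag lost its call without P3 replicate 3 or without P18 replicate 3 (adjusted p up to 0.0533). Oxidative phosphorylation had 1 of 23 higher and 1 lower (3 and 1 adjusted over the list alone), at adjusted p = 0.0469 and 0.273 with an estimated correlation. The starburst list itself was 3 of 8 higher and 3 lower, the lower ones being Megf10 and the transcription factors Isl1 (-0.91) and Sox2 (-0.97). None of the lists was called with an estimated correlation. For voltage-gated ion channels the estimate of -0.017 lay below the preset 0.01, so correlation between genes does not account for that loss. With an estimated correlation camera is also limited by the few residual degrees of freedom of the 6 arrays.

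The changes in the cell types overlapped. Of 13617 genes, 458 were higher with age in both the Arc trend and starburst cells, against 95.4 expected (Fisher's exact test, one per direction, p = 1.37e-244), and 342 were lower in both, against 122 expected (p = 1.24e-96). Dcx, Sox4, Stmn2, Socs2 and Zfp57 were lower and Sparcl1, Pcp4, Mgarp, Vsnl1 and Faim2 higher in both sets of genes named by rule. Of 863 genes called in both, 63 changed in opposite directions. The comparisons share no array, and genes are not independent.

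At P3, starburst cells were set against Arc cells of P2 to P4 to find genes that separate the types early. Starburst cells had more Isl1, a LIM-homeodomain transcription factor (6816288), by at least 6.55 ± 0.14 (SE, n = 3 and 3), at adjusted p = 1.18e-11. Isl1, Sox2, Vcan, Megf10, Slc18a3 and Chat lay below background in Arc cells, so their differences are lower bounds. They also had more Megf10 (5.04), Vcan (4.53), the transcription factor Sox2 (4.19), Slc18a3 (3.81) and Chat (2.47), whereas Slc5a7 did not differ detectably (-0.01, adjusted p = 0.975). Npy, a neuropeptide, was higher in starburst cells by 3.58, and Kdr, a VEGF receptor, by 3.09. Arc cells had more Plppr5, a phospholipid phosphatase-related membrane protein (6900768), with a difference of -6.23 ± 0.16 (SE) as starburst minus Arc. The transcription factors Meis2 (-5.40), Lhx9 (-4.91) and Nr4a2 (-4.01), the phosphatase gene Ptprk (-5.32), the Slit receptor gene Robo1 (-4.53) and Gad2, a GABA-synthesizing enzyme (-3.06), were likewise higher in Arc cells. Arc itself differed by -1.40 at adjusted p = 0.00295, a call lost with single Arc arrays (adjusted p = 0.240, the highest over the alternatives). In all, 698 genes were higher and 771 lower in starburst cells, of which 217 and 280 by at least 2-fold. The count of 1469 was 931 without the Arc P4 array, 2470 with Arc P1 to P5 and P16 to P20 as partners, where the balance turned to 1385 higher and 1085 lower, and 339 with the single arrays of Arc P3 and P18.

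At P18, against Arc cells of P17 to P19, starburst cells had more Slc5a7 by at least 5.50 ± 0.17 (SE, n = 3 and 3), Isl1 by 5.49, Slc18a3 by 5.10 and Chat by 4.43 ± 0.21 (SE), the last at adjusted p = 7.78e-09; all 4 lay below background in Arc cells, so these are lower bounds. Grm3, a metabotropic glutamate receptor (4.88), Slc24a4 (4.80), Hecw1, a ubiquitin ligase (4.90), and Pcdh10, a protocadherin (4.67), were also higher. Arc cells had more Plppr5 (-6.08), Neto2, an auxiliary subunit of kainate receptors (-5.63), the synaptic organizers Cbln2 (-5.50) and Cbln1 (-4.27), Olfm3 (-5.33), Meis2 (-4.97) and Gad2 (-3.10). The GABA and glycine receptor list had 3 of 14 genes higher and 5 lower (3 and 5 adjusted over the list alone) and the glutamate receptor list 4 of 15 higher and 7 lower (5 and 8 adjusted over the list alone), neither called by camera (adjusted p = 0.333 and 0.209). Among their genes, Gabra3 (-5.00) and Gabrb2 (-3.44) were lower and Gabrd (3.14), Gabra4 (2.79) and Glra4 (2.97) higher in starburst cells. Arc itself differed by -1.14 at adjusted p = 0.00712, which rose to as much as 0.233 over the alternatives and missed 0.05 after quantile normalization and with single Arc arrays. In all, 1320 genes were higher and 1500 lower in starburst cells, of which 321 and 509 by at least 2-fold. The count of 2820 was 1586 without Arc P19, 1813 without Arc P18, 1852 without starburst P18 replicate 1, and 2177 higher and 1755 lower with Arc P1 to P5 and P16 to P20 as partners, where the balance turned. It was 707 with the single arrays of Arc P3 and P18.

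All 8 measured starburst genes, which include the driver gene Chat, were higher in starburst cells at P18 (8 adjusted over the list alone), including Megf11 (2.72) and Tenm3 (2.06), at adjusted p = 3.98e-14 and 0.00169 with an estimated correlation. Tenm3 lost its call with single Arc arrays (adjusted p = 0.135, the highest over its alternatives). Pan-amacrine genes had 6 of 13 lower and none higher (7 adjusted over the list alone), among them Meis2, Gad2, Pax6 (-1.49) and Tfap2b (-1.26), at adjusted p = 5.17e-06 and 0.0633 with an estimated correlation. In the Arc age trend, cyclic loess gave 3 pan-amacrine genes higher and 6 lower. Voltage-gated ion channels had 6 of 24 higher and 11 lower (6 and 12 adjusted over the list alone), with Kcnc1 at 1.71 and Kcnd3 at -2.82, at adjusted p = 0.0418 and 0.285 with an estimated correlation. Cholesterol synthesis genes had 6 of 13 lower (6 adjusted over the list alone), such as Msmo1 (-1.97) and Sc5d (-1.01), at adjusted p = 0.0418 and 0.517 with an estimated correlation. Microglia genes had 5 of 10 higher (5 adjusted over the list alone), such as the cathepsin gene Ctss (1.12), at adjusted p = 0.0329 and 0.379 with an estimated correlation. Endothelial and mural genes had 4 of 13 higher (6 adjusted over the list alone), among them Cspg4 (0.58) and Kdr (0.73), at adjusted p = 0.0395 and 0.517 with an estimated correlation. After cyclic loess 1 microglia gene, 2 endothelial and mural genes and 3 cholesterol genes were called. With single Arc arrays Sc5d, Ctss and Cspg4 lost their calls. Of 6 lists called, 2 remained in number without Arc P19 and 3 without starburst P18 replicate 1. Cell type, mouse line, fluorophore and the batch label of the samples go together and cannot be told apart.

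**Figure D4:**
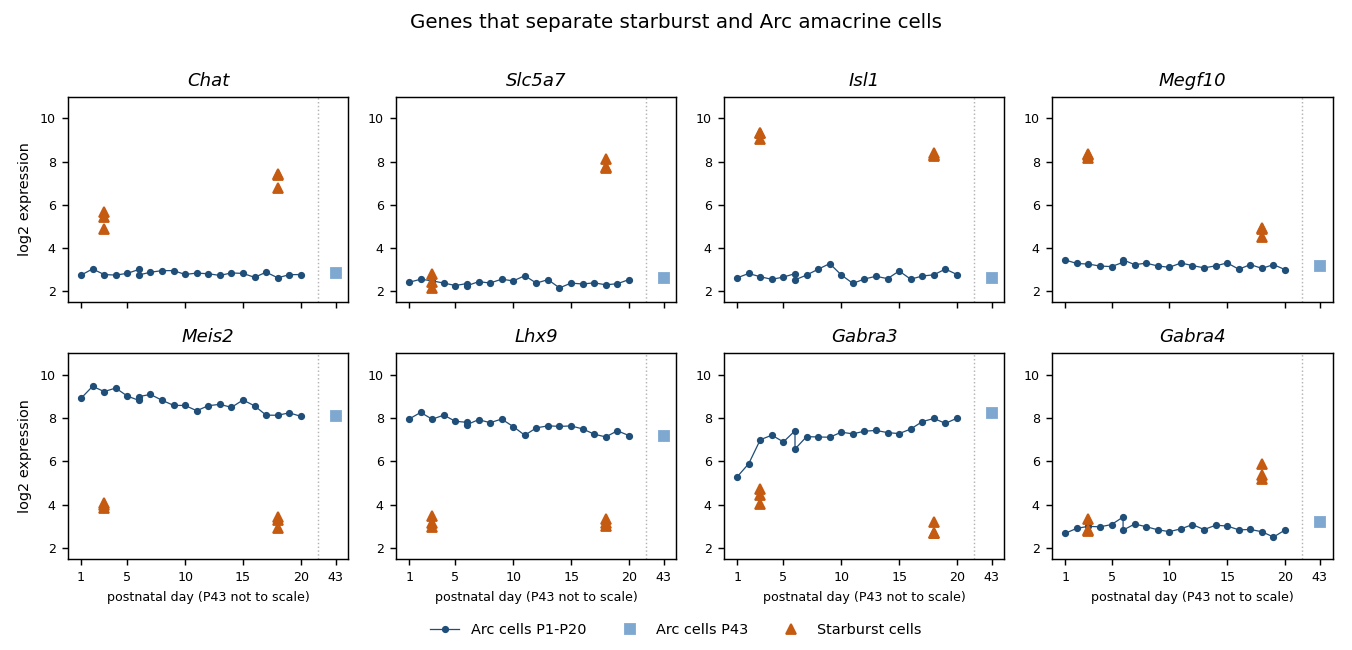
Log2 expression of 8 genes in each array against postnatal day, with symbols as in the plot of the Arc age course. Chat, Isl1 and Megf10 were higher in all starburst arrays than in all Arc arrays, Slc5a7 and Gabra4 at P18 only, and Meis2, Lhx9 and Gabra3 were lower in all starburst arrays.

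The change between the ages differed between the cell types for 548 genes, 227 with a more positive and 321 with a more negative change in starburst cells, of which 177 and 248 by at least 2-fold. Slc5a7 had a difference of 5.51 ± 0.24 (SE, 12 arrays) at adjusted p = 4.35e-08, being below background in Arc cells at both ages and in starburst cells at P3. Chat (1.96, adjusted p = 0.00173), Gabra4 (2.76) and Glra4 (2.91) likewise had a more positive change in starburst cells. Vcan (-4.41), Megf10 (-3.44), Olfm3 (-3.87) and Gabra3 (-2.70) had a more negative one, Gabra3 rising with age in Arc cells and falling in starburst cells. Slc18a3 had a difference of 1.30 that did not pass (adjusted p = 0.114). With the single arrays of Arc P3 and P18 the count was 91, and Chat and Glra4 were not called (adjusted p = 0.145 and 0.163, the highest over their alternatives).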

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

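The comparison of developmental changes, the splits of arrays and the tests of scaling, of a batch and of a steady change were planned before their results were seen. The tests of rod RNA and of sort purity, and the use of cyclic loess on the olfactory receptor genes, were chosen after seeing the result.

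The developmental change differed between starburst and Arc cells for 548 genes, by a test of the difference itself. Among genes with a more positive change in starburst cells were Slc5a7 at 5.511, Chat at 1.963 and the muscarinic receptor gene Chrm4 at 3.947. So had Zmat4 (5.26), Slc24a4 (4.594), Pcdh18 (4.156), Hecw1 (4.143), the chemokine gene Cxcl14 (3.766) and the receptor genes Grm8 (3.458), Glra4 (2.911), Gabra4 (2.761) and Gria3 (2.348). A more negative change in starburst cells was seen for Vcan (-4.415), Olfm3 (-3.868), Tshr (-3.478), Megf10 (-3.438), Glul (-3.4), Epb41l3 (-3.362), Tmeff1 (-3.308), Thy1 (-2.978), Sema3a (-2.88), Gabra3 (-2.697), Dkk3 (-2.186) and Clu (-1.527). With single Arc arrays Glul, Clu, Chat and Glra4 lost their calls (adjusted p = 0.302, 0.132, 0.145 and 0.163), and Gria3 did with Arc P1 to P5 and P16 to P20 (0.0906), each the highest over its alternatives. Cell type goes together with mouse line, fluorophore and batch label, and a batch difference that is the same at both ages cancels in this contrast. No age group of either cell type held 4 to 10 samples, and the windows of 7 arrays pool different days, so no array was tested as an outlier.

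Other splits of the arrays were tried for each comparison. For the Arc age trend 1 of 100 splits, the real one, gave as many genes (5137, highest other 354). For middle against early it was 1 of 100 (67, highest other 6), and for late against middle 2 of 100 (914, highest other 979). For the age trend, chance is excluded at a share of 0.05 as the source of a relation with age as such. Shuffled ages leave the age trend in the residual spread, so this share does not clear each of the 5137 genes. Other splits of the windows mix arrays of different ages, so the age trend enters either their residual spread or their contrast. The shares of the windows bear on a relation with age as such. They cannot exclude chance as the source of the 67 or the 914 genes. Starburst P18 against P3, and starburst against Arc cells at P3 and at P18, have 10 splits each, too few for a share under 0.05; 1 of 10 gave as many genes in each (1178, 1469 and 2820, highest other 0, 0 and 0). For the difference of changes 3 of 100 splits gave at least 548 genes, a share under the bound of 0.05 set beforehand. These splits exchange cell type labels, so the large difference between cell types enters either their residual spread or their contrast. The share therefore cannot exclude chance as the source of the 548 genes. The highest other splits called 1143 and 1019 genes. The first exchanged the cell type labels of 1 of 3 arrays per cell type at the early and 3 of 3 at the late age, the second those of 2 of 3 early and 0 late arrays. By this construction they hold part of the difference between cell types, a structure of the samples.

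More genes fell (3132) than rose (2005) with age in Arc cells. The 708 olfactory receptor genes, used here as a background set, had a median change of -0.16 (-0.1582), with 66 called lower and 0 higher by limma. After cyclic loess it was -0.03, with 7 higher and 11 lower, and the split of all genes was 2048 higher and 1728 lower; with P1 to P16 alone, fewer arrays and the deposited scaling it was 1150 higher and 816 lower at a median of -0.14. Scaling of dim values by the normalization may explain the excess of lower calls. A loss of many weakly expressed transcripts with age stays open as a biological explanation and was not tested.

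Of 18 rod photoreceptor genes 11 were called higher with age in Arc cells and 2 in starburst cells, and in both the list lost its call with an estimated correlation (adjusted p = 0.181 and 0.102). Across the 17 rod genes other than Gnat1, the changes in the cell types correlated with r = 0.874 (permutation p = 2e-05), against 0.507 over all genes, and 1.85% of random lists of rod size and level reached it. RNA of rods carried into the sorted samples may explain this, although gates on scatter and pulse width would remove debris and doublets; no other list holds a rod gene. At Arc P17 to P19 Gnat1 stood at 7.14 and Sag at 4.75, but levels of different probe sets cannot be compared. For a general loss of sort purity, the bipolar median change differed from that of rods by -0.677, past the bound set against this cause. The medians were 0.44 for rod, -0.24 for bipolar, -0.14 for cone and -0.17 for Muller glia genes. Those of the other cells lie near the -0.16 of the olfactory receptor genes, so scaling of dim values could hide a rise. After cyclic loess 3 bipolar genes were higher and none lower, 2 cone genes higher and none lower, and 3 Muller glia genes higher and 2 lower. The test therefore cannot decide. A maturing retina with more rod RNA, and expression in amacrine cells themselves, stay open too. Whether the recessive photoreceptor degeneration mutation named in the labels of the Arc-EGFP mice affected these samples was not tested. In the single Arc P43 array Gnat1 stood at 6.91.

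Between P13 to P16 and P17 to P20 257 genes were called, against 250 at the boundary of P9 and P10 and 0 to 3 at the others. At an unadjusted p under 0.05 by limma the count was 1434 genes, against 2106 at the boundary of P9 and P10. It was 2134 at the boundary of P11 and P12, where 0 genes were called. By that count the boundary after P16 does not stand out. Tested for an array batch that began after P16, the share of olfactory receptor genes called was 0.0413 of the share among genes above the median. The bound written beforehand would have counted this against a batch, but it was wrong, because these genes lie near the floor, where a batch shift can be hidden. A steady change with no step is not excluded by the 257 genes either, since a comparison of neighbouring windows also calls genes that change steadily. A batch, a steady change and a developmental step cannot be told apart here.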

How the results depend on the processing

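Quantile normalization, array-median centring, P1 to P16 alone, the lists without single arrays and the check of replicate pairing were chosen after seeing the data; the other alternatives were planned. Of 2424 values for 250 gene results, with the lowest and highest change standing for single arrays left out, 2355 kept their direction and side of the threshold, 69 kept the direction and lost the call, and 0 reversed. These genes were chosen for the text, many for their large changes, so the share says little about the other calls. Losses without further single arrays, such as those of Sag and Snap25, are not among the 69. The calls lost were those of middle against early and, in at least 1 alternative, Socs2, Tac1, Neurod4, Msmo1, Insig1, Rims1 and Tfap2b in the Arc trend, Slc18a3, Gpr37, Sag and Snap25 in starburst P18 against P3 (the last without P3 replicate 1 or 3, adjusted p up to 0.0594), Arc and Pax6 at P3, Arc, Gnat1, Sc5d, Ctss, Cspg4, Tenm3 and Aqp4 at P18, and Gria3, Glul, Chat, Glra4 and Clu in the difference of changes.

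With genes above the median mean, counts were 3422 for the Arc trend and 278 for middle against early, where fewer genes were tested. A minimum log2 change of 1 left 989 for the Arc trend, 19 for middle against early, 93 for late against middle, 605 for starburst P18 against P3, 497 and 830 for the cell types at P3 and P18, and 308 of 800 shared genes, by construction. Array weights gave 0 for middle against early and 1511 for late against middle, quantile normalization 110 for middle against early, and other windows 0 and 2181; the cause was not tested. The spline gave 3229 and P1 to P16 gave 1966 for the Arc trend, the latter with fewer arrays. A fit over all 28 arrays gave 2522 for starburst P18 against P3, more of them lower than higher, with more residual degrees of freedom. For the cell types at P3, Arc P1 to P5 and P16 to P20 gave 2470 with more arrays. Single Arc arrays gave 339 at P3, 707 at P18 and 91 for the difference of changes, with fewer arrays, a lone array being assumed to vary like the other groups. An estimated correlation left 2 lists of 9 in the Arc trend, 0 of 8 in starburst cells and 1 of 6 at P18, and genes above the median mean left 2 at P18.

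Leaving out 1 array gave 4168 to 5605 for the Arc trend, 0 to 272 for middle against early, 580 to 1162 for late against middle, 810 to 908 for starburst P18 against P3, 931 to 1507 at P3, 1586 to 2873 at P18 and 391 to 588 for the difference. Called lists at P18 ranged from 2 to 8. Leaving out 1 array, the similarity to P43 kept r between 0.913 and 0.942. Replicate numbers do not pair the starburst arrays: same-numbered pairs correlated with r of 0.0455, 0.0183 and -0.0443, and a replicate block gave 1060 genes. Genes near background (95th percentile 3.47 in Arc and 3.91 in starburst cells) allow no statement that they are absent or unchanged.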

Other observations

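The values of this part were looked at after the data were seen.

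Some genes of the Muller glia list rose in Arc cells while the list as a whole did not. Glul rose by 3.61 and Dkk3 by 2.54 and Clu by 2.45, while Vim fell by 1.20 and Gpr37 fell by 2.06. In starburst cells Glul stood at 3.49 at P3 and 2.89 at P18.

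The Arc P43 array is a single sample and was used in no gene test. There the cholesterol synthesis genes had a median 0.25 above the late window, at percentile 99.98 of 10000 random lists of that size and level, and 5 of 13 lay above every array of P1 to P20, among them Msmo1 at 8.10. Synaptic vesicle genes had a median difference of 0.05 (percentile 99.03), lens genes 0.21 (percentile 98.64), GABA and glycine receptor genes 0.11 (percentile 95.47) and neurite growth genes -0.17 (percentile 4.37). The random lists hold unrelated genes, whereas genes of a list can move together in a single sample. For cholesterol synthesis the estimated correlation in the Arc age trend was 0.28. The percentiles therefore overstate the evidence, and these lists were picked from all that were ranked. Of all genes 5.31% lay above every earlier day. Tac1, which fell between P1 and P20 from a mean of 6.05 in the early to 3.77 in the late window, stood at 5.89 at P43.

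In a polynomial of age over the Arc arrays, limma called 4997 genes for the linear term, 0 for the quadratic (176 at an unadjusted p under 0.05, where chance gives 681) and 49 for the cubic term (1477 unadjusted). The mean square of the quadratic term was 0.0287, that of the residuals 0.0431, and 200 random directions gave 0.0329 to 0.0696.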
